A study of Bos taurus with 20 samples.

How the data were processed

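The tissue was intercaruncular endometrium of the uterine horn on the side of the conceptus or of ovulation, from 4 pregnant and 6 control heifers on day 18. Each of the 10 RNA samples was labelled with phosphorus-33 and hybridised to both arrays, per the labels' protocols, so the 20 samples are 10 animals measured on 2 arrays. Per the labels, both arrays of an animal shared a hybridisation vial and all arrays were processed together, except that the 18KO array of pregnant 316 was repeated later with 2 other samples and its values were placed by their ratios to these. Each array carries 1536 clones of a subtracted library as spotted PCR products.

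The deposited values are spot intensities on a linear scale; how the authors subtracted background and scaled the columns is not given in the sources used here. Intensities ran from 0 to 685.73 on the 18KB and from 0 to 632.83 on the 18KO array, with column medians from 1.39 to 3.18 and from 1.67 to 3.90, so the columns do not share a median. They were used as deposited, raised to a floor of 0.01 and taken to log2; 92 values of 42 clones on the 18KB array and 103 values of 31 clones on the 18KO array lay at or below that floor. No column repeated another, and log2 columns of one group correlated at 0.935 to 0.982 on the 18KB and at 0.94 to 0.98 on the 18KO array. The number of other columns of per-sample values in the tables was 0.

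Clones were named through the deposited platform's gene table, which can be old. It lists 211 clones of the 18KB array, 202 with 1 symbol and 9 with several, and leaves 1325 without a name here; for the 18KO array it lists 141, 137 with 1 symbol (5 of them with the symbol GRP given for a pair of gene identifiers) and 4 with several, and leaves 1395. By gene identifier 200 of the 202 and 137 of the 137 were found in the RefSeq table of assembly ARS-UCD2.0 under the same symbol, and the file's symbol was kept for PNN and BOLA. No genome coordinates are given, since the build behind the clones is not stated in the sources used here. Clones with 1 symbol were averaged per gene on the log2 scale, giving 86 and 72 genes; no gene had clones of opposite sign, but clones of 1 gene differed in size, from 2.88 to 5.85 for the 12 clones of ISG15.

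Naming was not random. Per the series design text, the authors sequenced clones that they had called with SAM at a fold of 2 and a false discovery rate of 1%, after inspecting the spots by eye, and some additional ones. Accordingly 84.7% of named clones but 11.2% of clones without a name were called here on the 18KB array, and 45.3% against 3.66% on the 18KO array. The Benjamini-Hochberg adjustment over named genes is therefore lenient, and an adjustment of gene p-values together with those of all clones without a single name was added after seeing the data.

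Pregnant and control animals were compared per clone and per gene with lmFit and eBayes of limma 3.58.1 (statmod 1.5.0) in R 4.3.3, with Benjamini-Hochberg adjustment; a clone or gene was called at an adjusted p under 0.01 and a fold of at least 2. Lists of at least 3 genes were tested with fry, whose directional p asks whether the genes of a list move, on balance, one way, adjusted over the 11 list tests of both arrays; camera with an estimated and with a preset correlation of 0.01, which set a list against the other named genes, were alternatives. Per-animal means of lists were compared by two-sided exact permutation over all 210 splits. Genes on both arrays were tested for an interaction of status and array, without and with the animal as a block. The numbers in the labels are those of the animals, so they pair the 2 arrays of an animal. Over the 10 shared genes the deviations of the arrays from their group means correlated at 0.352 to 0.928 in 9 animals and at -0.08 in pregnant 316. Arrays of different animals were not correlated in this way, so these values do not test the pairing. Whether the later hybridisation of the 18KO array of pregnant 316 bears on its value was not tested. Pregnant and control animals share no number. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

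Before the data were examined, gene lists and markers of other cell types were fixed, and so was the rule for named genes: per array, the 15 called genes with the largest change in each direction whose groups do not overlap, and from each list up to 4 genes with the smallest p, called or not. The genes on both arrays are all given. Other genes were named after their values were seen: PLSCR2, COL6A2, LOC615277, FBLN1, TIMP3, TUBB, TUBB6, TUBA1A, SERPINH1, HSPA5, KDELR2, SERPINA14, CRYGS and STC1. The alternatives tried were equal column medians, quantile normalization, 1 factor per animal from both arrays, a floor at the 10th percentile, a pseudocount at the 5th percentile, leaving out the dimmest 25% of clones, other thresholds, a SAM statistic over all 210 splits, a trended and robust prior, array weights, age in months as a covariate, the brightest clone per gene, both arrays in 1 fit, and leaving out each animal in turn; leaving out control 427 and pregnant 448 together, and the 18KB arrays without values at or below 0.01 (control 427, pregnant 426 and 447) as a block, were added after seeing the data.

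The tests were tested on simulated data made from the means and spreads of each array's 1536 clones, with 200 clones changed. On the 18KB array limma recovered 26%, 66%, 84% and 96% of clones changed by 1, 1.5, 2 and 3 on the log2 scale and called 1 unchanged clone; on the 18KO array it recovered 16%, 58%, 70% and 98% and called 0. Of 100 sets of unchanged clones, fry gave a p under 0.05 in 9 on the 18KB and 4 on the 18KO array. The noise was drawn independently for each clone and animal, without correlated genes or shifts of whole columns. These rates therefore need not hold for the real lists and counts.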

Results

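Endometrium from the caudal part of the uterine horn was taken from heifers on day 18, when the bovine conceptus has not yet attached and secretes interferon tau, the signal by which cattle recognise pregnancy. The tissue of 4 pregnant heifers, in which a conceptus was found and removed, was compared with that of 6 control heifers, which had been inseminated with sperm-free fluid and were at the same day of the cycle. Each RNA was labelled with radioactive phosphorus and hybridised to 2 spotted cDNA arrays of 1536 clones each. The 18KB array carries clones of a subtracted library enriched for transcripts that are more abundant in pregnant animals, and the 18KO array those of a library enriched for the opposite direction. The 20 columns of spot intensities had medians from 1.39 to 3.18 on the 18KB array and from 1.67 to 3.90 on the 18KO array, and the number of animals limits the precision of every value. Values below are log2 fold changes, pregnant minus control, with their standard error, from limma over 4 pregnant and 6 control animals.

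The first comparison asked which transcripts of the pregnancy-enriched library differed between pregnant and control endometrium. Interferon-stimulated genes were higher in every pregnant animal than in any control by their mean level, and all 27 genes of this group with a name on the 18KB array rose. ISG15, a ubiquitin-like protein that is attached to other proteins, was 28.8-fold higher in pregnant animals (log2 4.85 ± 0.46, adjusted p = 5.14e-06), and UBA7, the enzyme that activates ISG15, was 18.4-fold higher (4.20 ± 0.42, adjusted p = 6.04e-06). Outside this group, PLET1, a surface protein of epithelia, had a log2 fold change of 6.83 ± 0.84, or 4.90 with a floor at the 10th percentile of all values (0.32), and PENK, the precursor of enkephalin peptides, rose 13.7-fold (3.78 ± 0.69). Collagen genes fell, among them COL1A1 (-2.02 ± 0.45) and COL3A1 (-1.69 ± 0.37).

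The 27 interferon-stimulated genes, represented by 89 clones, had a median log2 fold change of 2.45, from 1.11 for PLSCR2 to 4.85 for ISG15. All 27 also passed when adjusted over the list alone. The antiviral GTPases MX1 and MX2 rose 10.6-fold and 9.32-fold, the antiviral enzyme RSAD2 16.4-fold (log2 4.04, or 3.09 with a floor at the 10th percentile), RIGI, a sensor of viral RNA, 9.54-fold, and IFIT3 8.67-fold (log2 3.12, or 2.45 with that floor). PARP12 rose by 2.80 ± 0.29, IFI6 by 2.44 ± 0.26 and RTP4 by 2.90 ± 0.54 on the log2 scale (RTP4 1.41 with that floor). Clones of 1 gene differed in size, and the brightest clone alone gave 2.88 for ISG15, 5.14 for IFIT3 and 4.39 for IFI6. IRF9, part of the transcription factor complex that interferons activate and the one named gene of the interferon signalling list, rose 3.12-fold (1.64 ± 0.33, limma adjusted p = 0.000449), a call lost when the median of each column was set equal (0.81) or after quantile normalization (0.82). The mean log2 level of the 27 genes per animal was 2.64 ± 0.38 (SD, n = 4) in pregnant animals and 0.05 ± 0.51 (SD, n = 6) in controls, a difference of 2.59 with a two-sided exact permutation p of 0.00476, the smallest that the 210 splits can give (0.0081 after Benjamini-Hochberg adjustment over 17 list means). Control 427 had a mean of 1.06, against -0.35 to 0.02 in the other controls. Its 18KB column and those of pregnant 426 and 447, the pregnant animals with the higher means (2.87 and 3.06, against 2.32 in both others), held 0 values at or below 0.01, where the other columns held 9 to 16. With these 3 arrays as a block, chosen after seeing the data, all 27 genes were still called (median 2.26). The directional list test, fry, gave an adjusted p of 5.14e-05. Set against the other named genes of the array, the list had an adjusted p = 0.684 by camera with an estimated correlation. That comparison had few unchanged genes to draw on, since 78 of the 86 named genes were called. The authors sequenced chiefly clones that they had found to differ in these same samples. The count and the p-values of this list, and of each list below, are therefore not independent evidence of its direction.

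**Figure D1:**
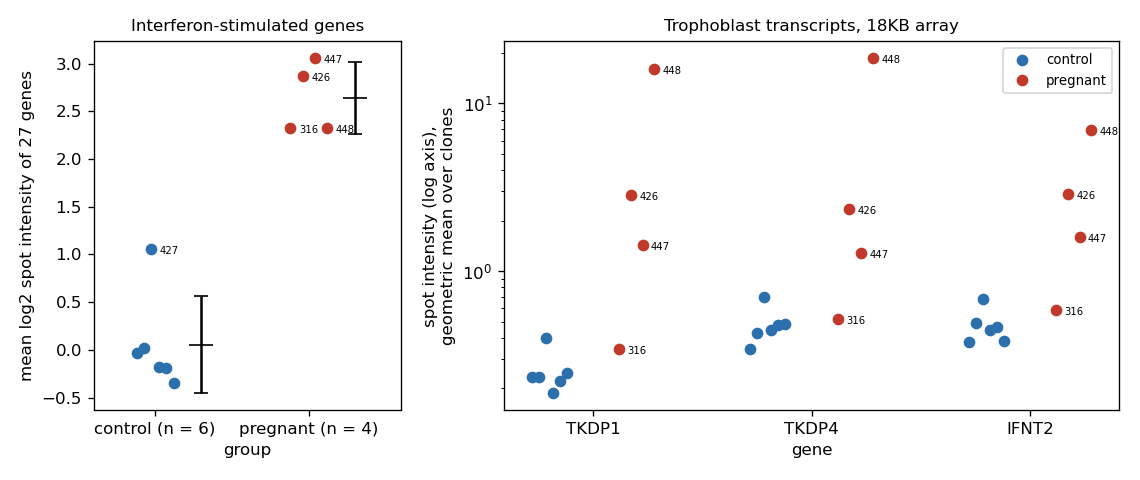
The left panel plots the mean log2 spot intensity of 27 interferon-stimulated genes per animal on the 18KB array, with group mean and SD as black bars; the right panel plots the spot intensity of TKDP1, TKDP4 and IFNT2 per animal on a log axis, with pregnant animals numbered. Control 427 lies at 1.06 in the left panel, above the other controls and below every pregnant animal, and pregnant 448 has the highest value of all 3 trophoblast genes.

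Genes of antigen presentation and of complement were higher in pregnant endometrium. All 4 named antigen presentation genes rose, and 4 passed when adjusted over the list alone: TAP1, a subunit of the transporter that loads peptides onto class I molecules (1.81 ± 0.24), BOLA, of the bovine major histocompatibility complex (1.55 ± 0.25), B2M, the class I light chain (1.48 ± 0.24), and CD74, the invariant chain of class II molecules (1.28 ± 0.24). The fry test gave an adjusted p of 2.16e-05 (adjusted p = 0.79 with an estimated correlation), and all 4 calls were lost when column medians were set equal, with CD74 at 0.45 and TAP1 at 0.98. All 3 complement genes rose and passed adjusted over the list alone: C4A (2.65 ± 0.36), the protease C1R (1.71 ± 0.26) and SERPING1, the inhibitor of the first complement component (1.64 ± 0.24). Their adjusted p was 5.14e-05 with fry (adjusted p = 0.79 with an estimated correlation), and with equal column medians 1 of the 3 was still called.

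Among genes for secreted and growth-regulating proteins of the uterus, the 3 named on the 18KB array rose, and all 3 passed adjusted over the list alone. Besides PLET1 these were DKK1, a secreted Wnt antagonist, at 10.3-fold (3.37 ± 0.39, or 2.72 with a floor at the 10th percentile, under which all 6 controls lay), and MEP1B, a subunit of the metalloprotease meprin, at 4.78-fold (2.26 ± 0.35). The fry adjusted p was 4.03e-06 (adjusted p = 0.684 with an estimated correlation). PLET1 in controls had intensities from 0.02 to 0.28, near the bottom of the scale. FABP3, a carrier of fatty acids and the one named member of the transporter list, rose 16.3-fold (4.03 ± 0.68, limma adjusted p = 0.000127). Other large rises were those of WIPF3, a protein that binds the actin regulator WASP (4.31 ± 0.75, or 1.75 with the floor at the 10th percentile), NUPR1, a nuclear protein induced by stress (2.89 ± 0.26), and the locus LOC511531 (2.98 ± 0.39). The brightest clone of NUPR1 alone gave 1.38.

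Of 7 named genes of the extracellular matrix on the 18KB array, 5 fell and 2 rose, and all 7 passed adjusted over the list alone. The genes that fell encode fibrillar collagens (COL1A1, COL1A2 at -1.73 ± 0.43, COL3A1) and collagen VI chains (COL6A1, COL6A2), and those that rose were AGRN, a basement membrane proteoglycan (2.21 ± 0.31), and TGM2, an enzyme that cross-links proteins (1.71 ± 0.34, or 0.88 and not called with equal column medians). The list's median was -1.26 and its mean -0.54. The fry test gave an adjusted p of 0.19 for a shift to one side (adjusted p = 0.153 with an estimated correlation). The list passed as lower with equal column medians (adjusted p = 0.00175) and by camera with a preset correlation (adjusted p = 4.29e-05). The 3 collagen genes that also served as stroma markers fell together (median -1.73, fry adjusted p = 0.00569, adjusted p = 0.153 with an estimated correlation), and 3 of 3 passed adjusted over the list alone. FLNA, an actin cross-linking protein (-1.87 ± 0.33), the splicing factor TRA2B (-1.37 ± 0.32), the tubulin TUBB4B (-1.16 ± 0.24) and SEC61A1, a subunit of the protein channel of the endoplasmic reticulum (-1.06 ± 0.28), were also lower in pregnant animals. The call of SEC61A1 was lost without pregnant 448 or control 330 (-0.94 to -0.99).

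Transcripts of the trophoblast, the outer layer of the conceptus, were found in the endometrium of pregnant animals in very different amounts. The trophoblast Kunitz domain genes TKDP1 and TKDP4 and the interferon tau gene IFNT2 were called higher (3.14 ± 0.76, 2.31 ± 0.73 and 2.16 ± 0.52), and 3 of 3 passed adjusted over the list alone, but their values in pregnant animals overlapped those of controls, with pregnant 316 inside the control range. TKDP1 had a geometric mean intensity of 16.1 in pregnant 448, 2.85 in 426, 1.43 in 447 and 0.341 in 316, against 0.187 to 0.401 in controls. IFNT2 was 6.95 in pregnant 448 and 0.586 to 2.86 in the other pregnant animals. The sizes of all 3 rises thus rested in part on pregnant 448. The list's fry adjusted p was 0.02 (adjusted p = 0.979 with an estimated correlation, and 0.0664 with fry after column medians were set equal), and all 3 calls were lost with equal column medians or quantile normalization. The call of TKDP4 was also lost without pregnant 426 or without any 1 of the controls, with log2 fold changes of 2.22 to 2.42, and with the 3 arrays without values at or below 0.01 as a block (2.35), and TKDP4 had 1.31 without pregnant 448. At the level of clones, 7 of their 26 clones were called.

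In all, 326 of the 1536 clones of the 18KB array passed an adjusted p of 0.01 and a 2-fold change, 315 higher and 11 lower in pregnant animals, and of 86 named genes 78 were called, 69 higher and 9 lower. Values of the 2 groups did not overlap in 72 genes. Chance gives this in 0.952% of unselected genes, a rate that is no comparison for genes sequenced chiefly because they differed between these animals. The median log2 fold change of all clones of this array was 0.44, so the direction of small changes depended on the scaling. With equal column medians the median became -0.39, the called clones split into 152 higher and 174 lower, and 51 named genes were called, 39 higher and 12 lower. With quantile normalization the median was -0.26 and the split 178 to 139. With 1 factor per animal from both arrays it was 0.20. The 27 interferon-stimulated genes lay above 0 under each of these scalings, but 23 of them were called with equal column medians (median 1.62) and 23 after quantile normalization. Setting column medians equal took 0.83 off every log2 fold change of this array. Adjusted together with the clones without a name, a step chosen after seeing the data, 74 genes were called, without COL6A2, LOC615277, SEC61A1 and TKDP4.

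The second comparison asked which transcripts of the library enriched for controls differed. Expression of OXTR, the receptor for oxytocin, the hormone that elicits the prostaglandin pulses of luteal regression, was 12.6-fold lower in pregnant endometrium over its 6 clones (-3.65 ± 0.39, adjusted p = 2.6e-06). Its size depended on low values, since all 4 pregnant animals lay under the 10th percentile of the array (0.37), and it was -1.93 with a floor there. TNC, a matrix glycoprotein, was 9.57-fold lower (-3.26 ± 0.59), GADD45G, a stress-induced growth regulator, 9.44-fold (-3.24 ± 0.36, or -2.41 with that floor) and the kinase PLK2 6.36-fold (-2.67 ± 0.36). Of 13 named matrix genes 11 fell and none rose. PENK (3.20 ± 0.48) and SERPING1 (2.47 ± 0.35), which are also on the other array, rose here too; SERPING1 was the one complement gene with a name on the 18KO array.

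Matrix genes formed the largest of the fixed lists on the 18KO array, with a median of -1.73, and 11 of 13 passed also adjusted over the list alone. Besides TNC, the genes with the smallest p were COL6A3 (-2.44 ± 0.45), COL1A1 (-2.28 ± 0.44) and COL4A2, a basement membrane collagen (-1.79 ± 0.36). COL3A1 (-1.73 ± 0.41) and TIMP1, an inhibitor of matrix metalloproteases (-2.19 ± 0.46), fell as well, while FBLN1 (-1.06) and TIMP3 (-0.87) were not called. TIMP1 had an intensity of 48.9 in control 449 against 8.27 to 12.2 in the other controls. The mean of the 13 genes was 2.39 ± 0.52 (SD, n = 4) in pregnant animals and 4.14 ± 0.45 (SD, n = 6) in controls, with a two-sided exact permutation p of 0.00476. The fry adjusted p was 0.000872 (adjusted p = 0.764 with an estimated correlation). These p-values are not independent evidence either, since the genes carry names chiefly because they differed in these samples. When gene p-values were adjusted together with those of all clones without a name, a step chosen after seeing the data, 5 of the 13 were still called.

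Of the stroma markers, those that fell were matrix genes themselves. Of 6 stroma markers, 4 fell (COL1A1, COL1A2, COL3A1 and COL6A3), NR2F2, a transcription factor of stromal cells, rose (1.52 ± 0.39) and FBLN1 was not called; 5 passed adjusted over the list alone, and fry gave an adjusted p of 0.0204 (adjusted p = 0.979 with an estimated correlation). Both smooth muscle markers fell and both passed adjusted over the list alone: the actin ACTA2 (-1.41 ± 0.36) and the kinase MYLK (-1.58 ± 0.39). The one epithelial marker, the tight junction protein CLDN4, rose (1.96 ± 0.58, limma adjusted p = 0.00601).

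Of 3 adhesion and junction genes, CLDN4 and the tetraspanin CD81 (1.35 ± 0.42) rose and CLDN10 was not called (-1.93 ± 0.74, limma adjusted p = 0.0223); 2 passed adjusted over the list alone, the median of 1.35 and the mean of 0.46 were both positive, and the fry adjusted p was 0.0833 (adjusted p = 0.153 with an estimated correlation). It became 0.0146 without control 449 and 0.000767 with equal column medians. Of the genes of prostaglandin synthesis and hormone receptors, OXTR fell, the only one to pass adjusted over the list alone, and PTGS2, the inducible cyclooxygenase, had a value of -0.47 ± 0.59 (limma adjusted p = 0.447). In one clone of OXTR all 4 pregnant animals lay at the floor of 0.01. Of 7 genes of the uterine secretory list, 4 fell: the retinol carrier RBP4 (-1.26 ± 0.37), the calcium-binding protein S100G (-1.40 ± 0.42), the peptide precursor GRP (-1.16 ± 0.37) and ANXA2, an annexin (-1.16 ± 0.37). The other 3, CRYGS, SERPINA14 and STC1, were not called. None of the 7 (0) passed adjusted over the list alone, and the fry adjusted p of 0.0231 was not kept (adjusted p = 0.97 in the opposite direction with an estimated correlation). It was 0.0595 without pregnant 316, 0.0724 without pregnant 447, 0.0543 without pregnant 448 and 0.0507 without control 404. RBP4, GRP and ANXA2 lost their calls with equal column medians and with quantile normalization.

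**Figure D2:**
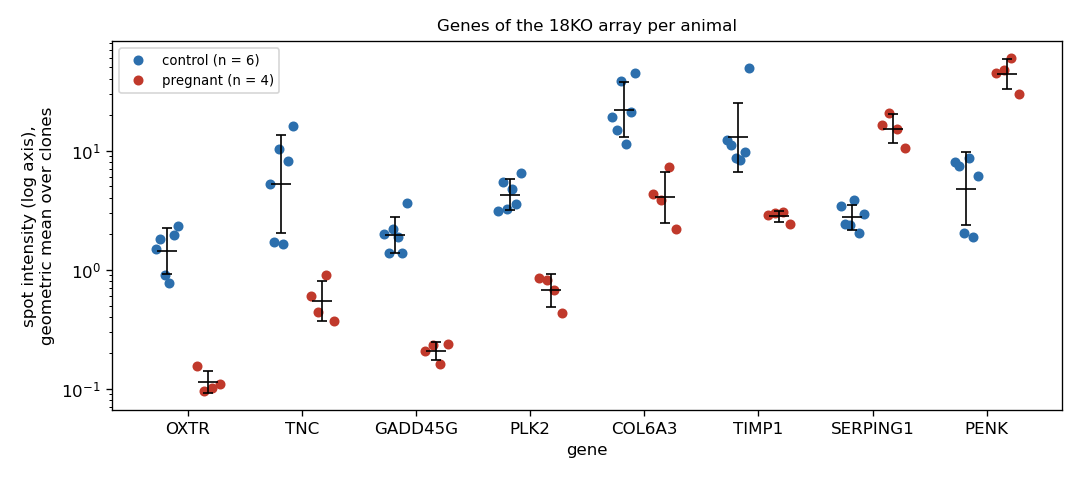
Spot intensity per animal, on a log axis, of 8 genes of the 18KO array, as the geometric mean over the clones of each gene; points are animals, black bars the mean and SD of the log2 values. The 4 pregnant animals lie below all 6 controls in OXTR, TNC, GADD45G, PLK2, COL6A3 and TIMP1 and above them in SERPING1 and PENK.

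Further genes with large decreases were OLFM2, an olfactomedin (-3.81 ± 0.69, or -0.47 and not called with a floor at the 10th percentile, under which all 4 pregnant animals and 3 controls lay), PMEPA1, a transmembrane protein induced by transforming growth factor beta (-2.08 ± 0.41), CKAP4, a membrane protein of the endoplasmic reticulum (4.01-fold lower), the protease ADAMTS4 (-1.94 ± 0.52), the phosphatase DUSP5 (-1.83 ± 0.52, not called with equal column medians, nor at -0.79 with that floor) and the glycosyltransferase A4GALT (-1.76 ± 0.37). TXNIP, an inhibitor of thioredoxin (1.53 ± 0.44), and EPAS1, a hypoxia-inducible transcription factor (1.45 ± 0.41), rose. With age as a covariate TXNIP (1.18), EPAS1 (1.10), CLDN4 (1.42) and CD81 (1.10) were not called.

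On the 18KO array 115 of 1536 clones were called, 18 higher and 97 lower in pregnant animals, and 50 of 72 named genes, 7 higher and 43 lower; the groups did not overlap in 49 genes, where the chance rate of 0.952% for unselected genes again does not apply. The median log2 fold change of all clones was -0.06; with equal column medians it was 0.27 and the called clones split 82 to 93, and with quantile normalization 0.15 and 53 to 104. With 1 factor per animal the median was -0.29. The count of genes rested on few animals and on the adjustment: it was 23 without pregnant 316, whose array was hybridised later than the others, 21 without pregnant 426, 20 without pregnant 448 and 33 without control 440, and 14 when adjusted together with the clones without a name. Those 14 were A4GALT, COL1A1, COL4A2, COL6A3, FLNA, GADD45G, OLFM2, OXTR, PENK, PLK2, PMEPA1, SERPING1, TIMP1 and TNC, and every other call named here for the 18KO array was lost under that adjustment. It used p-values of the fit to named genes. In the limma fit to all 1536 clones some of the lost genes had called clones and others had none. The single clones of ACTA2 (adjusted p = 0.00412) and CKAP4 (0.0089) were called there, and that of ADAMTS4 (0.0206) was not. Calls of single genes also rested on single animals. ADAMTS4, ACTA2, MYLK, NR2F2, TXNIP, EPAS1, DUSP5, CLDN4, CD81, S100G, RBP4, GRP and ANXA2 were each not called without 2 or more of the animals taken singly, and COL3A1 without pregnant 448 (-1.36). Of the genes taken by the naming rule on this array, those that lost their call numbered 13 without pregnant 426, 11 without pregnant 448, 10 without pregnant 316, 8 without control 440, 7 without pregnant 447 and 4 without control 449. The count of clones was 76 without pregnant 316, 65 without pregnant 426 and 58 without pregnant 448.

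The third comparison set the direction of the called clones against that of the library they came from. On the 18KB array 96.6% of called clones (exact 95% interval 94.0% to 98.3%) were higher in pregnant animals, and on the 18KO array 84.3% (76.4% to 90.5%) were lower (two-sided Fisher's exact test, p = 2.46e-65). Clones of 1 gene are not independent, so this p describes these clones only. With equal column medians the shares were 46.6% and 53.1%. That scaling removes most of any shift that the clones of an array share, so these shares cannot tell such a shift from an effect of scaling. Under it the genes on both arrays differed between the arrays by a median of -1.18, against -0.019 as deposited.

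The fourth comparison used the 10 genes present on both arrays, which were measured again in the same animals from clones of another library. PENK, SERPING1 and TXNIP were higher in pregnant animals on both arrays, and COL1A1, COL1A2, COL3A1, COL6A1 and FLNA lower on both; SEC61A1 and SLC25A25 had the same sign without passing on both. SERPING1 and TXNIP on the 18KB array and COL6A1 on the 18KO array were not called with equal column medians (0.81, 0.61 and -0.78) or after quantile normalization (0.87, 0.88 and -0.81). The median difference between the arrays was -0.019 (95% bootstrap interval -0.15 to 0.22, over genes, not animals). No gene (0 of 10) responded differently by the limma interaction test at an adjusted p of 0.05, and 1, SERPING1, had an unadjusted p under 0.05 (0.0282), with 1.64 on the 18KB and 2.47 on the 18KO array. This test treated the 2 arrays of an animal as independent. With the animal as a replicate block the count was also 0, and the unadjusted p of SERPING1 was 0.0107. In the blocked fit all 10 genes had the same standard error, 0.314, so it held no error of the single gene.

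**Figure D3:**
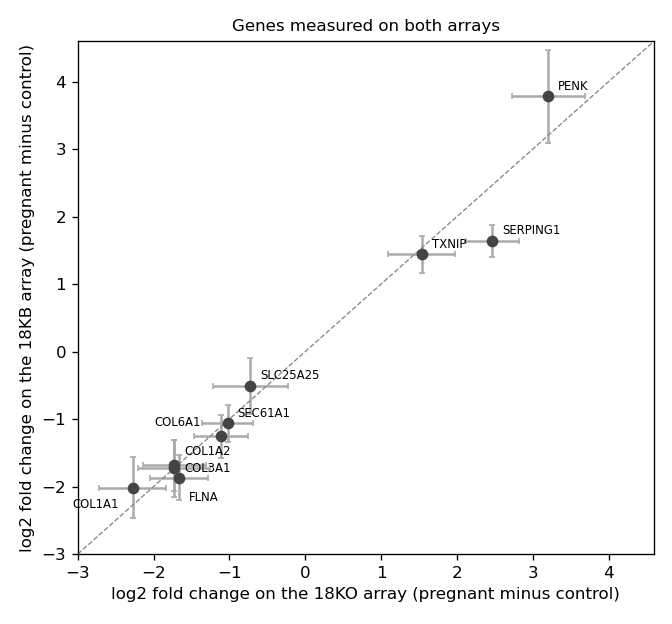
Log2 fold change, pregnant minus control, of the 10 genes present on both arrays, with the 18KO array on the horizontal and the 18KB array on the vertical axis; bars are standard errors and the dashed line marks equal values. All 10 genes have the same sign on both arrays.

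Lists of chemokines and cytokines, proliferation, ribosome and translation, mitochondrially encoded genes, and markers of blood cells, leukocytes and endothelium had 0 named genes on either array and were not tested.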

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

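The 6 tests on control 427 in this part were chosen after its values were seen. In 162 groups of 4 or 6 animals (named genes and list means), 16 held an animal far from the others, where chance gives about 8.1 for independent groups. The groups are not independent, since they share animals and the list means hold the same genes, so the excess is no test. Of the 16, 10 concerned control 427 as the highest of the 6 controls. The gap to the next control, as a share of the range of the controls, was 0.801 for ISG15 (8.52 against 1.34 to 1.93), 0.669 for UBA7 (3.51 against 0.75 to 1.25), 0.63 for MX1, 0.828 for RIGI (1.73 against 0.528 to 0.648), 0.698 for MX2, 0.649 for IFIT3, 0.644 for IFI6 and 0.737 for the mean of the interferon-stimulated genes. It was 0.643 for TKDP1 (0.401 against 0.187 to 0.245) and 0.743 for the mean of the 3 trophoblast genes.

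Of the 27 interferon-stimulated genes, 26 were higher in control 427 than the mean of the other 5 controls, by a median of 1.24 (0.92 to 1.59, 95% bootstrap interval) on the log2 scale. The low end of its 18KB column also stood apart, with 0 values at or below 0.01 and a 10th percentile of 0.42 (9 to 14 values and 0.225 to 0.24 in the other controls), as in pregnant 426 and 447 (0 values, 0.575 and 0.63), but signal or background of the array falls short of the difference: all other clones lay higher by a median of 0.27 (0.24 to 0.30), and the 50 other clones nearest in brightness to each gene by 0.36 (0.26 to 0.44). RNA of a pregnant animal mixed into the sample stays open. It would cover 1 share of the gap to the pregnant mean in all clones that rose. In a fit without this animal the share was 16.5% (13.4% to 18.4%) over 88 interferon-stimulated clones. It was 17.3% (12.2% to 21.9%) over 235 clones not named as members of the interferon lists. Of these, 176 have no name and may include interferon-stimulated clones, so the likeness of the 2 shares decides nothing. The interval was 21.2% to 29.7% for those 176, and the median was 2.51% (1.38% to 4.05%) for the 59 with a name. Clones were named chiefly after calls by the authors with this animal as a control, which can lower the 2.51%. The 3.81% (-2.51% to 9.80%) of named genes called with it as a control can be lowered in the same way. A pregnant animal under a control label is argued against by 372 clones not named as interferon-stimulated and called in a fit without this animal. Control 427 lay nearer to the pregnant mean at 24.2% (19.9% to 28.9%) of them. The share was higher, 39.5%, for the 177 18KB clones without a name, which may include interferon-stimulated ones. The 9.90% (4.85% to 17.5%) of named genes called with it as a control can be lowered by that choice of genes. No biological explanation was tested, the labels record no state of this animal that bears on interferon, and its slightly higher trophoblast level rests on intensities near the bottom of the scale.

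Other animals that stood apart are given as values. PLET1 was 1.72 in pregnant 447 against 14.8 to 21.2 in the other pregnant animals (0.857 of the range). TIMP1 was 48.9 in control 449 against 8.27 to 12.2 (0.781), and DUSP5 was 0.08 in pregnant 316 against 0.2 to 0.22 (0.906). Control 449 was the lowest control for the mean of antigen presentation genes on the 18KB array (0.755) and the highest on the 18KO array for the means of the uterine secretory list (0.66) and of the smooth muscle markers (0.645); its 18KO column also had the highest median intensity, 3.90.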

How the results depend on the processing

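The adjustment of genes together with clones without a name, leaving out control 427 and pregnant 448 together, and the 3 arrays of the 18KB set without values at or below 0.01 as a block were chosen after seeing the data. With that block 301 clones and 77 genes were called, 285 and 76 of them also called without it, and the median of all clones was 0.34. The number of clones called on the 18KB array lay between 264 and 394 against 326 under all settings except an adjusted p of 0.05 without a fold limit (598), and named genes between 57 and 82 against 78 except with equal column medians (51); the cause was not tested. These were not the same clones: 163 of the 326 called with equal column medians and 189 of the 317 after quantile normalization were also called as deposited. On the 18KO array the 115 clones became 175 with equal column medians, 239 with 1 factor per animal from both arrays, 69 with a floor at the 10th percentile, 269 at an adjusted p of 0.05 without a fold limit, 194 with SAM and 62 without control 427 and pregnant 448, and 58 to 114 with each animal left out in turn; the cause was not tested, other than the fewer animals. The 50 genes became 14 when adjusted with the clones without a name, 18 without control 427 and pregnant 448, and 20 to 51 with each animal left out. The 14 rest on p-values of the fit to named genes, which differ from those of the fit to all clones. The share of called clones in the library's direction was 46.6% and 53.1% with equal column medians and 90.2% and 93.7% with 1 factor per animal (18KB and 18KO). Lists called by fry, 6 on the 18KB and 3 on the 18KO array, became 0 and 0 by camera with an estimated correlation and 3 and 1 with a preset one. Camera asks another question, since it sets a list against the other named genes. Of those genes most were called themselves, with 8 of 86 and 22 of 72 named genes not called. How far this accounts for the lost lists was not tested. Of the lists called with a preset correlation, 2 and 0 were also called by fry. The 1 on the 18KO array was adhesion and junction, higher (adjusted p = 0.0243). The uterine secretory list of the 18KO array turned its direction (adjusted p = 0.97 and 0.778). With a preset correlation the interferon-stimulated list passed at an adjusted p of 0.00281. The animal as a replicate block left the count of genes that differ between arrays at 0; it was run for that result alone. The interferon-stimulated mean differed by 1.76 to 2.79 under all its alternatives. No log2 fold change changed sign among the 68 genes taken by the naming rule, per array, which alone were followed singly; equal column medians ended 15 of their calls and quantile normalization 11. Low signal limits clones near the floor, among them OLFM2, OXTR, GADD45G, PLET1, WIPF3, RTP4, RSAD2, DKK1, IFIT3, TKDP1 and DUSP5.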

Other observations

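The tests on the trophoblast transcripts and on the shift of the 18KB array in this part were chosen after their values were seen, and so were the genes of the first paragraphs. The 4 tubulin genes with a name were lower in pregnant endometrium: TUBB4B on the 18KB array (-1.16 ± 0.24), and TUBB (-1.47 ± 0.35), TUBB6 (-1.54 ± 0.38) and TUBA1A (-1.36 ± 0.38) on the 18KO array, the latter 3 without a call when adjusted together with clones without a name. On the 18KO array SERPINH1, the chaperone of collagens (-1.46 ± 0.39), and the chaperone HSPA5 (-1.42 ± 0.42) were lower, again without a call under that adjustment. KDELR2, a receptor that returns proteins to the endoplasmic reticulum (-0.98 ± 0.37), and SEC61A1 (-1.02 ± 0.34) were not called there. They are named as single genes; no list of either kind was fixed or tested.

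Some transcripts varied widely between the 6 controls. The uterine serpin SERPINA14 had intensities of 85.5 in control 449, 42.7 in 330, 29.2 in 427, 8.52 in 440, 6.68 in 404 and 1.48 in 434, against 2.61 to 8.53 in pregnant animals. CLDN10 was 11.6 in control 440, 8.80 in 427 and 7.79 in 449 but 0.635 to 1.04 in the other controls, and 0.586 to 1.05 in pregnant animals. FABP3 was 0.15 in control 440, 0.33 in 427 and 0.47 in 449 and 1.23 to 1.76 in the others. These are values of single animals.

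Other splits of the 10 animals into 4 and 6 did not give counts like those of pregnancy. In 100 of the 210 splits, the real one included, 1 split gave as many called clones on the 18KB array (326, highest other 1), as many genes (78, highest other 1) and as many lists (6, highest other 0), and on the 18KO array as many clones (115, highest other 1), genes (50, highest other 7) and lists (3, highest other 0), in each case the real split. For the counts of clones the real split ranked first of the 100 drawn, which makes chance unlikely but does not exclude it. The low counts of the other splits are no measure of chance, since those splits mix pregnant and control animals within groups. For genes and lists the splits decide nothing, since the genes carry names chiefly because the authors had found them to differ under the real grouping.

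Trophoblast transcripts ranked the pregnant animals 448, 426, 447 and 316, and pregnant 316 lay close to the controls. All 26 clones of TKDP1, TKDP4 and IFNT2 had this order, which 4.88% of all clones of the array share. A higher signal of the array of pregnant 448 is argued against by the median of all other clones, which lay 0.27 below the other pregnant animals (-0.27, interval -0.30 to -0.24) while trophoblast clones lay 3.80 above. Different amounts of conceptus RNA left in the samples and expression of these genes in the endometrium itself both stay open: 100% of the 4 IFNT2 clones followed the order of TKDP1, but that order was part of the pattern already seen, and either source would give it. In all, 34 clones, 9 of them without a name, followed TKDP1 with a correlation over 0.9 across the animals.

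Most clones of the 18KB array were higher in pregnant animals, by a median of 0.44 and by 0.66 in the dimmest and 0.15 in the brightest 25% of clones. Scaling of this array apart from the 18KO array would move the genes on both arrays by the difference of the array medians, 0.50, but these differed by -0.019 (-0.15 to 0.22, an interval over genes, not animals), and by -1.18 once column medians were set equal. A factor per animal common to both arrays, as the whole cause, would give both arrays 1 median, but they differed by 0.50 (0.44 to 0.54, an interval over clones, not animals). The libraries were enriched for opposite directions, so their medians can differ with such a factor present. It therefore stays open as a part of the shift. An additive background as the whole cause would move the brightest 25% by 0.0097, and their median was 0.15 (0.09 to 0.21). An enrichment of the library for transcripts of pregnancy may remain as a biological hypothesis, which was not tested. Combinations of these technical causes were not tested either, and only 10 genes, chosen by the authors, tie the arrays together.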
